A study of Mus musculus with 9 samples.

How the data were processed

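Poly(A) RNA of ovary was measured by paired-end, strand-marked (dUTP) Illumina sequencing in 9 libraries, per the labels' protocols. The labels give the organism as mouse, strain Balb/c, and 3 treatments with 3 libraries each. These are Blank, POF (premature ovarian failure) and POF+BSHXF, where BSHXF is Bushen Huoxue Fang, a traditional Chinese herbal formula. How ovarian failure was induced, and the dose and time of the formula, are not given in the sources used here. Groups were taken from the treatment label and the replicate number from the sample title. Each of the 9 value columns was matched to a sample by the name of its group and its number. The columns named for treatment were matched to the samples titled with the formula's name, the only samples labelled as receiving it, and 0 columns were left without a sample.

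The authors deposited 1 table of whole numbers per transcript, with 1 column per library, whose column totals differ. They were taken here as estimated counts without normalization, because low values pile up at multiples of 4 and the submitters' processing notes name StringTie. That reading was not tested, and a plain tally of reads was not excluded. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, edgeR and DESeq2 were used, with no role or order named. The genome build, the annotation and the counting step are not given in the sources used here.

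The table holds 40807 transcript IDs, and all 40807 carry the prefix ENSRNOT, which Ensembl uses for rat transcripts, whereas the labels say mouse. Of these IDs, 0 were found in the mouse gene tables used here, and the file does not pair IDs with gene names. No transcript could therefore be named, summed to a gene or placed on a chromosome. Whether the reads came from rat, were mouse reads aligned to a rat reference, or belong to another experiment was not settled from the files, and every value below is conditional on that. The 27 gene lists fixed before the data were examined, for ovarian cell types, steroid synthesis, immune cells, stress and other processes, are lists of gene symbols. Of them, 0 could be tested, and gene-level statements are absent for the same reason.

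The estimated counts were used as deposited. Transcripts were kept by edgeR's filterByExpr (minimum count 10, minimum total 15, groups of 3), which left 20723 transcripts holding 99.9% of all counts. Of the 40807 transcripts, 13340 were at 0 in every library. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) with TMM normalization and robust dispersion. All 9 libraries entered 1 fit with 3 group means, which leaves 6 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over the 20723 transcripts of each comparison, and the threshold was 0.05. Levels are given as CPM, with library totals scaled by TMM, as mean ± SD of 3 libraries. Standard errors of log2 fold changes are the fold change divided by the square root of F. Correlations and principal components used log2 CPM with a prior count of 2.

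Transcripts were named by a rule fixed before the data were examined. A transcript past the threshold was named if its mean over the 9 libraries was at least 2 CPM and the libraries of the compared groups did not overlap, up to 8 in each direction. The rule would leave Ensembl IDs without a symbol unnamed, but because no ID here has a symbol, the IDs of the called transcripts are printed in place of names. The parts of the rule that need gene symbols could not be applied. The planned tests assumed genes, and they were run on transcripts. If the values are estimates, transcripts of one gene can share reads, so a change of one row can come from how reads were divided between rows. For each named transcript, its sum with the row listed directly after it in the table was therefore tested in the same way, a choice made after the values were seen. Whether such neighbours belong to 1 gene is not known.

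Total estimated counts ran from 41231313 to 58392086 per library. The limit set by a count of 0 was taken as 3 counts per library, and also as 12, 3 fragments of 4 counts each, a choice made after the values were seen. Such limits cover counting error only, and estimated counts are not independent reads. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. The common biological coefficient of variation was 0.766.

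The test was tested on simulated data drawn from the means and dispersions of the real libraries, with 50 transcripts changed at each of 4 sizes. The changed transcripts were drawn from those with a mean of at least 2 CPM, so the recovery does not cover less abundant ones. For POF against Blank (19912 transcripts), it recovered 4% of 2-fold, 28% of 4-fold, 72% of 16-fold and 78% of 64-fold changes, with 5 false calls. For POF+BSHXF against POF (19915 transcripts), it recovered 2%, 24%, 78% and 84% of the same sizes, with 2 false calls. For POF+BSHXF against Blank (19910 transcripts), it recovered 0%, 32%, 78% and 72%, with 10 false calls. With a dispersion of 0.04 in place of the real one, it recovered 100% of the changes of at least 4-fold in each comparison.

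Alternatives fixed before the data were examined were RLE normalization, no filter, a stricter filter (mean of at least 1 CPM and 10 counts in at least 3 libraries), DESeq2 1.42.0, limma-voom (limma 3.58.1), a fit of only the groups compared, other thresholds, a block for the replicate number and each library left out in turn. Chosen after the data were seen were a fit without POF replicate 1 and POF+BSHXF replicate 3 together, counts divided by 4, the first component of the within-group residuals as a covariate, each library of the group not compared left out in turn, and DESeq2 for opposite changes. Fits of fewer libraries repeated the filter and the normalization, and with 1 library left out they tested 21531 to 21703 transcripts. Overlaps between comparisons that share a group were set beside 20 simulations of unchanged groups. Dispersions in those simulations were estimated from the real libraries, 1 per transcript for all groups.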

Results

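Transcript levels were measured by RNA sequencing of poly(A) RNA from the ovary, in 3 groups of 3 libraries. The Blank group was the reference, the POF group modelled premature ovarian failure, the early loss of ovarian function, and the POF+BSHXF group was the same model given Bushen Huoxue Fang, a herbal formula. The design asks which transcripts differ in the model and which differ when the formula is given. Total estimated counts were 44164914, 52139969 and 58392086 in Blank replicates 1 to 3, 47018294, 41231313 and 54500112 in POF, and 57594506, 49264965 and 47008496 in POF+BSHXF. Each library held between 20637 and 22227 transcripts above 0. The transcript IDs carry a rat prefix although the labels say mouse, and the files do not pair them with gene names, so the transcripts below are given by ID.

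The libraries did not separate into 3 groups. Pearson correlations of log2 CPM across the 20723 tested transcripts were 0.861 to 0.879 within Blank, 0.796 to 0.840 within POF and 0.783 to 0.852 within POF+BSHXF, against 0.769 to 0.876 between libraries of different groups. The first principal component held 28.2% of the variance. POF replicate 1 (0.527) and POF+BSHXF replicate 3 (0.529) lay at one end. The Blank libraries (-0.399, -0.236 and -0.270) lay at the other with POF replicate 3 (-0.182) and POF+BSHXF replicate 1 (-0.259). POF replicate 2 (0.223) and POF+BSHXF replicate 2 (0.067) lay between. The Blank and POF libraries thus did not overlap on this component, while POF+BSHXF replicate 1 lay among the Blank libraries. The second component, with 12.1% of the variance, set Blank replicate 1 (0.796) apart. The 10 transcripts with the highest mean CPM over the 9 libraries were taken as 1 set. They took 27.8% ± 2.30 of the counts in Blank, 23.5% ± 2.44 in POF and 25.2% ± 2.30 in POF+BSHXF (SD, n = 3). Two-sided exact permutation tests gave p = 0.1 for POF against Blank, the smallest p that 3 against 3 allows, p = 0.4 for POF+BSHXF against POF and p = 0.3 for POF+BSHXF against Blank.

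**Figure D1:**
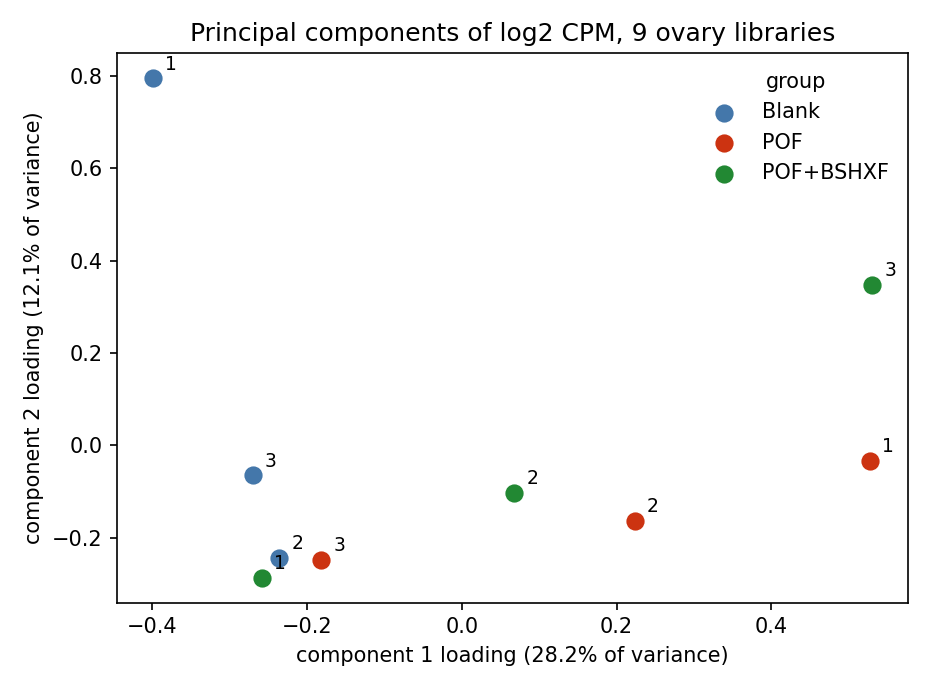
Positions of the 9 libraries on the first and second principal components of log2 CPM (axes without unit, share of variance in brackets), colored by group and numbered by replicate. POF replicate 1 and POF+BSHXF replicate 3 lie together at 0.527 and 0.529 on the first component, and the other libraries of their groups lie closer to Blank.

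In the model, 1 transcript was higher and 1 was lower than in Blank. ENSRNOT00000048407 rose from 0.860 ± 0.112 CPM in Blank to 11.5 ± 2.23 CPM in POF (SD, n = 3), a log2 fold change of 3.74 ± 0.27 (SE) with an edgeR adjusted p of 0.0125. Its estimated counts were 33 to 56 in the Blank libraries and 467 to 635 in the POF libraries. ENSRNOT00000046847 stood at 25.5 ± 3.38 CPM in Blank, with 861 to 1512 counts per library, and was listed at 0 in all 3 POF libraries (edgeR adjusted p = 0.00920). A count of 0 there allows up to 0.0615 CPM at 3 counts per library, and up to 0.246 CPM at 12 counts, which is 3 fragments if each entered the table as 4 counts. Both limits cover counting error only.

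The row listed directly after ENSRNOT00000046847 held 1078, 952 and 1613 counts in the POF libraries and 0 in the other 6. Tested alone, that row did not pass the threshold (edgeR adjusted p = 0.106 for POF against Blank and 0.0770 for POF+BSHXF against POF). The sum of both rows was 24.3 ± 3.90 CPM in POF and 25.5 ± 3.38 CPM in Blank, a log2 fold change of -0.07 ± 0.25 (edgeR adjusted p = 0.981). For ENSRNOT00000048407, the sum with its next row was 11.7 ± 2.30 CPM in POF and 1.42 ± 0.346 CPM in Blank. That sum differed by a log2 fold change of 3.03 ± 0.30, with an edgeR adjusted p of 0.163 that missed the threshold.

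Across the 20723 transcripts, edgeR gave an unadjusted p below 0.05 for 1622 (7.83%, where a share of 0.05 would be expected by chance). Of these, 948 were higher and 674 lower in POF. Among the transcripts that the filter kept in each refit (21537 to 21703), the count below 0.05 was 956 without Blank replicate 1 and 865 without Blank replicate 3. It was 944 without POF replicate 1 and 2462 without POF replicate 3. The POF and Blank libraries did not overlap for 16.6% of the transcripts, against 10% by chance. DESeq2 called 704 transcripts and limma-voom 1, and leaving out any 1 of the 6 libraries gave 5 to 10 edgeR calls. Both calls ended under limma-voom, that of ENSRNOT00000048407 at a log2 fold change of 3.70 (adjusted p = 0.0584, from 1.19e-38 to 0.505 over all alternatives) and that of ENSRNOT00000046847 at a fitted -11.30 (adjusted p = 0.707, from 4.52e-22 to 0.707), a size that depends on how the model treats a count of 0.

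With the formula, 1 transcript was higher and 1 was lower than in the model without it. ENSRNOT00000046847, at 0 in POF, stood at 24.8 ± 7.25 CPM in POF+BSHXF, with 757 to 1839 counts per library (edgeR adjusted p = 0.00933), beside 25.5 ± 3.38 CPM in Blank. The row listed after it was at 0 in the POF+BSHXF libraries, and the sum of both rows differed from POF by a log2 fold change of 0.03 ± 0.25. ENSRNOT00000047303 fell from 143.6 ± 15.9 CPM in POF to 9.63 ± 3.37 CPM in POF+BSHXF, a log2 fold change of -3.90 ± 0.29 (edgeR adjusted p = 0.0152). Its counts were 5336 to 8422 in POF and 263 to 726 in POF+BSHXF.

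The row listed after ENSRNOT00000047303 had 9763, 8033 and 6315 counts in the POF+BSHXF libraries, 0, 174 and 0 in the POF libraries and 105, 0 and 493 in the Blank libraries. Tested alone, it did not pass the threshold against POF (edgeR adjusted p = 1) or against Blank (0.782). The sum of both rows was 164.9 ± 17.7 CPM in POF+BSHXF and 145.0 ± 13.6 CPM in POF, a log2 fold change of 0.19 ± 0.14 (edgeR adjusted p = 1). ENSRNOT00000048407, called in the model, stood at 9.26 ± 1.68 CPM with the formula and 11.5 ± 2.23 CPM without it. That log2 fold change of -0.32 ± 0.25 was within the spread of the libraries (edgeR adjusted p = 1).

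**Figure D2:**
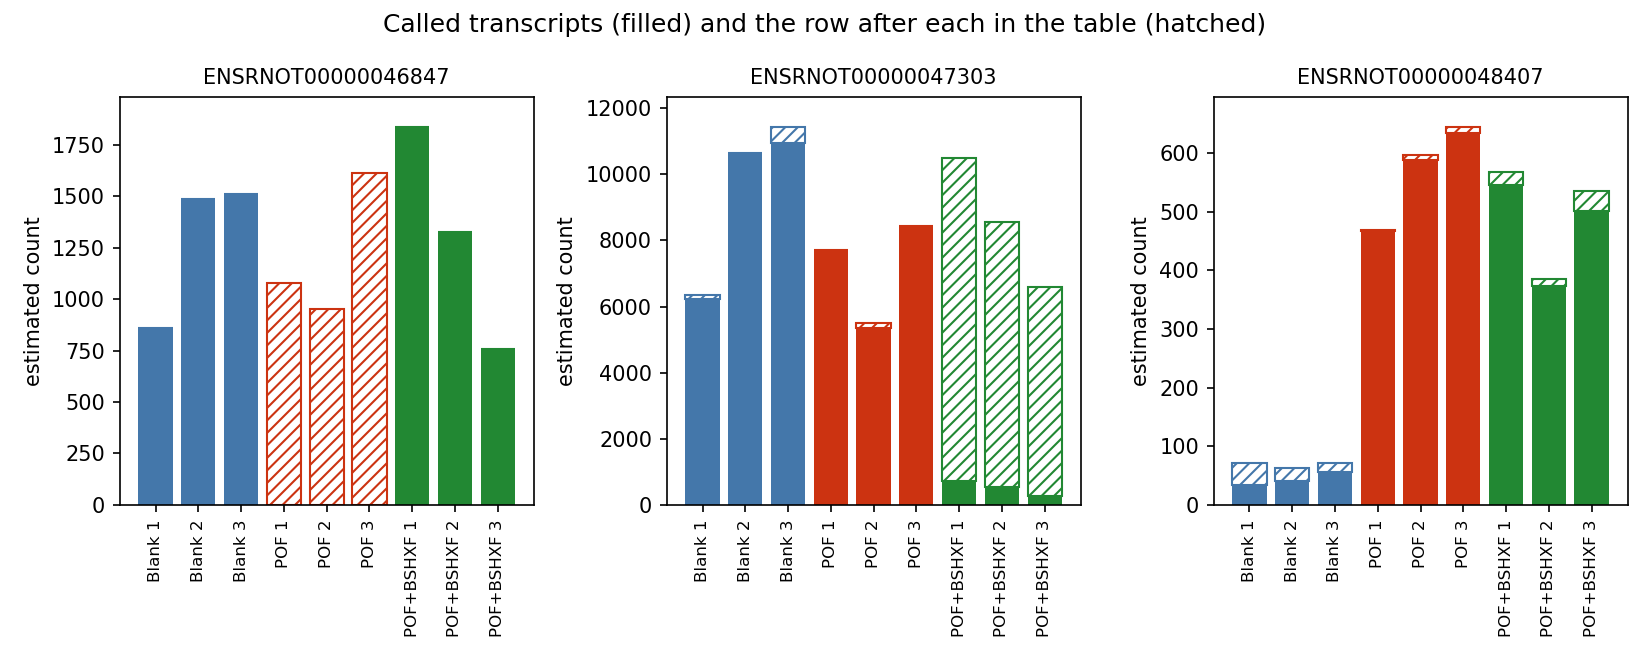
Estimated counts (vertical axis, from 0) of the 3 called transcripts in each library, 1 panel per transcript and 1 bar per library. The filled part is the transcript and the hatched part is the row listed directly after it, so that the full bar is their sum. ENSRNOT00000046847 is at 0 in the POF libraries, where the next row holds 952 to 1613 counts.

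In this comparison edgeR gave an unadjusted p below 0.05 for 567 of the 20723 transcripts (2.74%, below the share of 0.05 expected by chance). Among the transcripts that the filter kept in each refit (21531 to 21646), the count below 0.05 was 604, 603 and 912 without POF replicates 1 to 3. It was 747, 443 and 852 without POF+BSHXF replicates 1 to 3. The POF+BSHXF and POF libraries did not overlap for 6.36% of the transcripts, against 10% by chance. DESeq2 called 145 transcripts, limma-voom called 1, ENSRNOT00000047303, and a fit of only these 6 libraries called 0, with 364 at an unadjusted p below 0.05. In that fit the log2 fold change was -3.92 (edgeR adjusted p = 0.140) for ENSRNOT00000047303 and a fitted 13.28 (0.215) for ENSRNOT00000046847. The same 6 libraries set these sizes in both fits, so little change of size was possible. The adjusted p of these 2 transcripts ran from 4.70e-47 to 0.513 and from 7.17e-22 to 0.774 over all alternatives. Leaving out any 1 of the 6 libraries gave 4 to 9 edgeR calls. Blank replicate 2 and Blank replicate 3 enter the fit of all libraries through the shared spread, the filter and the normalization. Without 1 or the other, edgeR called 0 of 21575 and 21629 transcripts, with 501 and 446 at an unadjusted p below 0.05. Both transcripts then had an edgeR adjusted p of 0.0667 and 0.108.

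The third comparison gives what differed from Blank when the model received the formula. ENSRNOT00000048407 was higher in POF+BSHXF than in Blank by a log2 fold change of 3.42 ± 0.27 (edgeR adjusted p = 0.0215). ENSRNOT00000047303 was lower, at 9.63 ± 3.37 CPM against 184.2 ± 23.7 CPM, a log2 fold change of -4.26 ± 0.30 (edgeR adjusted p = 0.0180). Summed with its next row, the latter differed from Blank by -0.19 ± 0.14 on the log2 scale (edgeR adjusted p = 0.878). The sum for ENSRNOT00000048407 differed by 2.77 ± 0.29, with an edgeR adjusted p of 0.187 that missed the threshold. ENSRNOT00000046847 differed by -0.04 ± 0.28 (edgeR adjusted p = 1).

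Of the 20723 transcripts, 1213 had an unadjusted p below 0.05 in edgeR (5.85%, near the share of 0.05 expected by chance). Of these, 832 were higher and 381 lower in POF+BSHXF. Among the transcripts that the filter kept in each refit (21531 to 21703), the count below 0.05 was 759 without Blank replicate 1 and 673 without Blank replicate 3. It was 1923 without POF+BSHXF replicate 1 and 699 without POF+BSHXF replicate 3. The libraries of these groups did not overlap for 12.2% of the transcripts, against 10% by chance. DESeq2 called 480 transcripts, and leaving out any 1 of the 6 libraries gave 4 to 10 edgeR calls. The call of ENSRNOT00000048407 ended in 9 of 19 alternatives, among them without Blank replicate 1 (adjusted p = 0.0643), Blank replicate 2 (0.0519), Blank replicate 3 (0.0626) or POF+BSHXF replicate 1 (0.0519), under limma-voom (0.111) and in a fit of only these 6 libraries (0.143). Its log2 fold change was 3.28 to 3.52 and its adjusted p 2.05e-32 to 0.438 over all 19. That of ENSRNOT00000047303 ended in the fit of only these 6 libraries (adjusted p = 0.138, log2 fold change -4.25), with adjusted p from 1.59e-56 to 0.438 over all alternatives. Both calls also ended without POF replicate 2 or POF replicate 3, which enter through the shared spread, the filter and the normalization. There edgeR called 0 of 21633 and 21586 transcripts, with 998 and 1422 at an unadjusted p below 0.05.

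Both differences from POF were then compared by direction. ENSRNOT00000046847 was the 1 transcript called in both, lower in the model and higher with the formula, and its sum with the next row did not pass the threshold. The count of such transcripts was 0 under limma-voom, 0 without Blank replicate 2 or Blank replicate 3, up to 7 without another library (POF replicate 1) and 76 with DESeq2. At an unadjusted p below 0.05 in both comparisons, 228 transcripts changed in opposite directions and 2 in the same direction. Because the POF libraries enter both comparisons with opposite signs, unchanged groups already give such overlaps. The 20 simulations of unchanged groups gave 219 to 251, with a mean of 235, and independent lists would give 21.9. Across transcripts, which are not independent replicates, the log2 fold changes had a correlation of -0.39 and a covariance of -0.83. The simulated values were -0.50 and -0.94.

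The differences of POF and of POF+BSHXF from Blank were compared likewise. At an unadjusted p below 0.05 in both, 653 transcripts changed in the same direction and 2 in opposite directions. Simulated unchanged groups gave 213 to 261, and independent lists would give 50.5. The correlation of the log2 fold changes was 0.74 beside a simulated 0.50, and the covariance was 2.17 beside a simulated 0.96, a difference of 1.21. The simulated comparisons shared their Blank libraries too, so the simulated values already hold what shared controls give if all groups have the same dispersions. With 3 Blank libraries the controls could not be split with 2 in each part, so whether shared controls add more than that was not tested. The simulations drew each library independently and hold no deviations shared between libraries of different groups. They also gave all groups the same spread. In the data, correlations were 0.861 to 0.879 within Blank, 0.796 to 0.840 within POF and 0.783 to 0.852 within POF+BSHXF. How far this moves the simulated values of either pair of comparisons was not tested.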

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

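The 2 calls of each comparison were the same count under RLE normalization, no filter, a stricter filter and an added fold threshold, and both were shared in each. Other settings moved the counts, here given for POF against Blank, POF+BSHXF against POF and POF+BSHXF against Blank in this order. DESeq2 called 704, 145 and 480, both edgeR calls among them. Of its calls, 285, 82 and 246 were at 0 in some library and 147, 56 and 196 had overlapping groups. Limma-voom called 1, 1 and 3, of which 0, 1 and 1 were edgeR calls. A fit of only the groups compared called 9, 0 and 2, of which 2, 0 and 0 were calls of the fit of all 9 libraries, and the unadjusted p with the fold threshold called 980, 314 and 862.

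Each library left out in turn gave 3 to 10, 0 to 9 and 0 to 10 calls. The first had 9, 10 and 7 without Blank replicates 1 to 3 and 9, 5 and 5 without those of POF, the next 9, 4 and 5 without POF and 8, 9 and 6 without POF+BSHXF, and the third 8, 10 and 6 without Blank and 4, 9 and 6 without POF+BSHXF. Of the libraries not compared (chosen after the data were seen), leaving out POF+BSHXF gave 4, 4 and 3 in the first, Blank 4, 0 and 0 in the next and POF 3, 0 and 0 in the third. With a compared library left out, 2 to 7, 2 to 6 and 2 to 6 of the calls were at 0 in a library of the groups compared. Counted over all libraries of those groups, 0 to 6, 1 to 7 and 2 to 6 of the calls had overlapping groups. Why the counts moved was not tested.

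With the replicate number as a replicate block, edgeR called 0, 0 and 0, with 878, 382 and 554 transcripts at an unadjusted p below 0.05. Same-numbered libraries did not deviate together: 0 of 9 such pairs had a correlation above 0.1 (range -0.284 to 0.027). This gives no sign of a pairing by number. It cannot exclude one, since the first residual component, with 29.0% of the variance of these deviations, also shapes the correlations.

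Of the settings chosen after the data were seen, counts divided by 4 called 3, 3 and 3, and leaving out POF replicate 1 and POF+BSHXF replicate 3 together called 11, 15 and 10. The first residual component as a covariate called 176, 3 and 45, but it was estimated from the same libraries after removing group means, which lowers the residual spread by construction.

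For opposite changes, the 1 transcript became 228 at an unadjusted p below 0.05, 0 with limma-voom, 0 under the replicate block, 76 with DESeq2 (chosen after the data were seen) and 0 to 7 with each library left out. It was 2, 0 and 0 without Blank replicates 1 to 3, 7, 3 and 4 without the POF and 2, 2 and 1 without the POF+BSHXF replicates.

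No call changed sign in 19 alternatives each, which the no-overlap naming rule nearly ensures. ENSRNOT00000046847 passed the threshold in 17 against Blank and in 14 of POF+BSHXF against POF, ENSRNOT00000047303 in 15 and 15, and ENSRNOT00000048407 in 17 for POF and 10 for POF+BSHXF. Gene-list alternatives were not run, as no ID had a symbol, and a pseudocount applies to no count test. The simulated recovery of 2-fold changes, at most 4%, was set by the spread between libraries, since it was 60% to 72% with a dispersion of 0.04.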

Other observations

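The tests of summed adjacent rows, of adjacent rows at other distances and of multiples of 4 were chosen after the result was seen.

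Transcripts at 0 in a library were common among abundant ones. Of 14925 transcripts with a mean of at least 2 CPM, 1456 (9.76%) were at 0 in at least 1 library. Blank replicate 1 had 641 of them at 0, against 393 to 435 in the other libraries, and the smallest TMM factor (0.896). It also had the highest share of counts (30.5%) in the 10 transcripts with the highest mean over all libraries. Counting transcripts at 0 in exactly 3 libraries, the Blank trio had 11, the highest of the 84 possible trios, while the POF and POF+BSHXF trios had 2 each. Mixed trios had a median of 2 and at most 9.

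Adjacent rows of the table were more often strongly correlated, in both directions, than distant rows. Among 12999 pairs of adjacent tested rows, 4.75% had deviations from the group means with a correlation below -0.8, against 2.06% to 2.48% at distances of 10 to 500 rows, and 5.70% had one above 0.8, against 2.69% to 3.36%. The share with a correlation below -0.8 is what reads divided between neighbouring transcript entries would need. Of rows with an unadjusted p below 0.05 between groups, the share whose neighbour also had one in the opposite direction lay above that of distant rows only for POF+BSHXF against POF (3.21%, against 0.325% to 1.89%), and not for POF against Blank (4.29%, against 3.29% to 4.49%) or POF+BSHXF against Blank (2.81%, against 1.76% to 2.96%). A change in the summed estimate of adjacent rows was argued against for 2 of the called transcripts: the log2 fold change of the sum was -0.073 for ENSRNOT00000046847 between POF and Blank, and 0.19 for ENSRNOT00000047303 between POF+BSHXF and POF. Whether the reads were divided differently by the estimation step or the ovaries used another transcript of 1 gene stays open, and both would give these values.

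Low estimated counts piled up at multiples of 4. The value 4 was 2.31 times as frequent as the mean of the values 3 and 5 over all libraries (2.09 to 2.46 in single libraries), and 8 was 2.13 times as frequent as its neighbours. A candidate explanation is that each sequenced fragment entered as about 4 counts, which would make the counting error larger than the totals imply. No biological explanation was tested.

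POF replicate 1 and POF+BSHXF replicate 3 deviated from their group means together, with a correlation of 0.27 across transcripts. POF replicate 3 and POF+BSHXF replicate 1 did so with 0.26. Deviations sum to 0 within a group, so the second correlation follows in part from the first and is not a separate observation. No Blank library exceeded 0.0521 in size with a library of another group. Sequencing depth and the noise of low-abundance transcripts were argued against as the cause, since the first correlation was 0.277 after thinning to the smallest total and 0.259 over the 7353 transcripts of at least 20 CPM. Exchanged labels of POF replicate 3 and POF+BSHXF replicate 3 cannot be told apart from a difference between ovaries that both groups share. The exchange called 3 transcripts in edgeR against 2 as labelled, which met the mark set beforehand (more calls) by 1 call, but other splits of these 6 libraries also gave 3, and the demand that it exceed them was added after the counts were seen. It also gave 3210 transcripts at an unadjusted p below 0.05 against 567, and correlations of 0.837 to 0.851 within POF and 0.852 to 0.870 within POF+BSHXF, against 0.796 to 0.840 and 0.783 to 0.852 as labelled, all of which an exchange needs and a shared axis would give too. The called transcripts followed the labels as given. POF replicate 3 and POF+BSHXF replicate 3 had 0 and 757 counts of ENSRNOT00000046847, and 8422 and 263 of ENSRNOT00000047303. Both transcripts were picked by those labels, so they cannot decide the question. Transcripts at 0 in exactly 3 libraries were not picked by labels. They numbered 6 for POF replicates 1 and 2 with POF+BSHXF replicate 3, against 2 for the POF trio. For POF replicate 3 with POF+BSHXF replicates 1 and 2 there were 0, against 2 for the POF+BSHXF trio. As 1 count rose and the other fell, they do not decide it either. Ovaries that differ in a state the labels do not give could produce the same axis, and this was not tested.

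The groups as labelled were set against other splits of the same libraries. The 6 libraries of a comparison have 10 splits into 3 and 3, too few for a share under 0.05. POF against Blank had 2 calls, the highest other split had 6, and 8 of the 10 splits had as many. POF+BSHXF against POF had 2 calls, the highest other split had 3, and 4 of the 10 had as many. POF+BSHXF against Blank had 2 calls, the highest other split had 6, and 4 of the 10 had as many. At an unadjusted p below 0.05, POF against Blank had 1622 transcripts and the highest other split 1545, POF+BSHXF against Blank had 1213 and the highest other 1437, and POF+BSHXF against POF had 567, with 6 of the 9 other splits above it. The split of these last 6 libraries that puts POF+BSHXF replicate 3 with POF replicates 1 and 2, the exchange above, had 3210. That is several times the count of the real split, which points to a structure of the samples. Exchanging POF replicate 1 and POF+BSHXF replicate 1 instead gave 2018, also with 3 edgeR calls, so the values do not single out 1 exchange. DESeq2 called 107 to 534 transcripts in the other splits of POF against Blank, beside 704, 127 to 589 in those of POF+BSHXF against Blank, beside 480 and with 2 above it, and 129 to 1979 in those of POF+BSHXF against POF, beside 145 and with 6 of 9 others above it, the exchange at 1979.

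Over the 9 libraries, 60 of the 280 splits into 3 groups of 3 were drawn. A test of any difference among the groups called 3 transcripts as labelled, 27 of the 60 splits gave as many, and the highest other split gave 18, so chance cannot be excluded for that count. The 1 transcript called in opposite directions in both POF comparisons was reached by 25 of the 60 splits, with up to 6 in another split, so chance cannot be excluded there either.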
